A study of Drosophila melanogaster with 20 samples.

How the data were processed

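Gene expression was measured with single-channel Affymetrix Drosophila arrays in 20 samples of adult brain, 5 in each of 4 groups. Per the labels, whole brains came from wild-type Canton S flies with 5 brains per replicate, and sorted cells came from 10 to 15 brains per replicate, with males and females together. Per the labels' protocols, brains were dissociated with collagenase and DNase at 37 degrees and the fluorescent cells were sorted. Shaking was for 20 min at 1000 rpm for neurons, 20 min at 500 rpm for all glia and 5 min at 500 rpm for surface glia. RNA was then amplified and labelled with biotin, per the labels' protocols. The labels do not say separately whether whole brains were dissociated, so sorting, dissociation and genotype cannot be told apart from group in the comparisons with whole brain. The labels also give a different line and a different dissociation time or speed for each sort. Line and dissociation can therefore not be told apart from cell type in the comparisons between sorts either.

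The deposited table holds log2 values per probe set, normalized and summarised across arrays by the authors. RMA, affy and limma are named in the submitters' processing notes without versions or parameters. The log2 scale was taken from the method named and was checked against the range of the values. No scanner files were analysed here. The table has 18952 probe sets, of which 183 control probe sets were left out and 18769 were tested. The probe annotation gave 1 gene symbol for 13646 probe sets, several for 402 and none for 4721, and genes were named only from probe sets with 1 symbol, 11981 genes in all. The 1094 genes with several probe sets were represented by the probe set with the highest mean over the 20 arrays. Gene lengths came from the reference gene table, which held 11883 of the 11981 genes, and include introns.

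Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group in a fit of all 20 arrays, an empirical Bayes estimate of the spread and Benjamini-Hochberg adjustment over the probe sets of each comparison. A probe set was called at an adjusted p under 0.05 and a log2 difference of at least 1. The 6 comparisons were each pair of groups. A probe set was counted as higher or lower in surface glia than in each other group where all 3 comparisons called it the same way, and as higher in both glial sorts where both comparisons with neurons called it higher. A probe set was taken as within the negative controls in a group where it did not exceed the 95th percentile of the 44 negative control probe sets on any array of that group. Its difference from a group above the controls is then given as a lower bound, against the mean of that percentile. Where a group mean lay under this mean percentile but at least 1 array exceeded its own, the fitted difference is given and its size is uncertain. This holds for every such difference below, also where it is not repeated. The number of arrays limits the precision of each value, and errors are standard errors of the fitted difference or standard deviations between the 5 arrays of a group.

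The genes named were fixed by a rule. In each comparison they were the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between groups. For the genes that separated surface glia from each other group they were the 15 higher and 8 lower genes whose smallest difference was largest. From each gene list they were up to 5 members with the largest differences, members opposing the majority and a fixed set of markers. The markers Eaat1, w and ninaE had no probe set with a single symbol here. Gene lists, 33 in number, were written from general knowledge of fly brain biology. Those of cell types were pan-neuronal and synaptic genes, transmitter synthesis and transport, neuropeptides, ion channels, neurotransmitter receptors, pan-glial, astrocyte-like and ensheathing glia, cortex glia, surface glia and barrier, fat body, hemocyte, trachea, muscle and photoreceptor. Those of structures and transport were septate junction, basement membrane and extracellular matrix, innexins, lipid carriers and 4 kinds of transporter (ABC, sugar and monocarboxylate, amino-acid, organic anion and cation). Those of metabolism and other functions were cytochrome P450, glutathione and UDP-glycosyl transferases, glycolysis, oxidative phosphorylation, ribosomal proteins, heat and dissociation stress, immune response, circadian clock, cell cycle, sex-linked expression and eye pigment. Each list was tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation, among genes above the median level only and with fry. Its members were also adjusted over the list alone. Some genes are members of several lists, as vkg is of the surface glia and barrier and the basement membrane lists. The tests of such lists are therefore not independent.

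The fit was tested on simulated data made from the overall mean of each probe set and its spread within each group, with 200 probe sets changed in surface glia. For surface glia against neurons, 62% of rises and 60% of falls of 1.5 (log2) were called, and 84% and 94% of those of 3, with 69 of 18569 unchanged probe sets called. For surface glia against whole brain the shares were 62% and 62% at 1.5 and 84% and 94% at 3, with 46 of 18569 called. For surface glia against all glia they were 66% and 62% at 1.5 and 88% and 96% at 3, with 223 of 18569 called. For probe sets higher in surface glia than in each other group, 72 of 100 simulated ones were called with 15 unchanged ones, and for lower ones 76 of 100 with 20 unchanged ones. The camera test, run on a simulation of surface glia against neurons, called the 1 list that was shifted and 0 of the 29 others. The simulated probe sets varied independently and the lists were random. This run therefore cannot show how the preset correlation performs where the genes of a list vary together.

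Alternatives tried were a fit on only the arrays compared, the replicate number as a block, filters on dim probe sets, quantile normalization once more and centring each array. Others were a trend or robust estimate of the spread, array weights, other thresholds, 1 value per symbol, other probe sets of a gene and leaving out each array in turn. 3 further alternatives were added later and are described in the closing section. Outlying arrays were found by Dixon's ratio within groups of 5. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, matplotlib 3.10.9 drew the figures, and statmod 1.5.0 served the block fit.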

Results

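The data were single-channel expression arrays of the adult Drosophila melanogaster brain in 4 groups of 5 arrays. The groups were dissected whole brains of wild-type Canton S flies, and cells sorted for a green fluorescent protein from brains of 3 other lines: ELAV cells (neurons), REPO cells (all glia) and cells of a surface glia line. Each array gave log2 values of 18769 probe sets after 183 control probe sets were left out. Whole-brain arrays correlated with one another at 0.993 to 0.997 across probe sets, neuron arrays at 0.966 to 0.978, all-glia arrays at 0.763 to 0.937 and surface-glia arrays at 0.781 to 0.896. The median standard deviation of a probe set within a group was 0.15 in whole brain, 0.27 in neurons, 0.59 in all glia and 0.58 in surface glia. The lower quartile of the values was 3.83 ± 0.03 (SD, n = 5) in whole brain, 4.14 ± 0.09 in neurons, 4.53 ± 0.29 in all glia and 4.59 ± 0.23 in surface glia. The 44 negative control probe sets had a mean median of 2.65, 3.15, 3.79 and 3.96 in the same order. The 3′ minus 5′ difference of the eIF-4a control probe sets was 2.25 ± 0.23 in whole brain, 4.96 ± 0.47 in neurons, 4.24 ± 1.36 in all glia and 4.06 ± 0.32 in surface glia. For the GAPDH control probe sets it was 3.22 ± 0.15, 4.52 ± 0.53, 4.28 ± 0.62 and 3.65 ± 0.65 in the same order. All glia 4, with a mean correlation of 0.772 with its group, and surface glia 4, with 0.785, lay farthest from the other arrays of their groups. The first principal component held 40.8% of the variance and the second 15.3%. The labels place the replicates in different bottles and days, so the p-values measure the spread between these samples. They and the standard errors rest on 1 spread per probe set shared by the 4 groups, whose own spreads differed as given above. For most probe sets it is likely too small for surface glia against all glia and too large for neurons against whole brain.

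**Figure D1:**
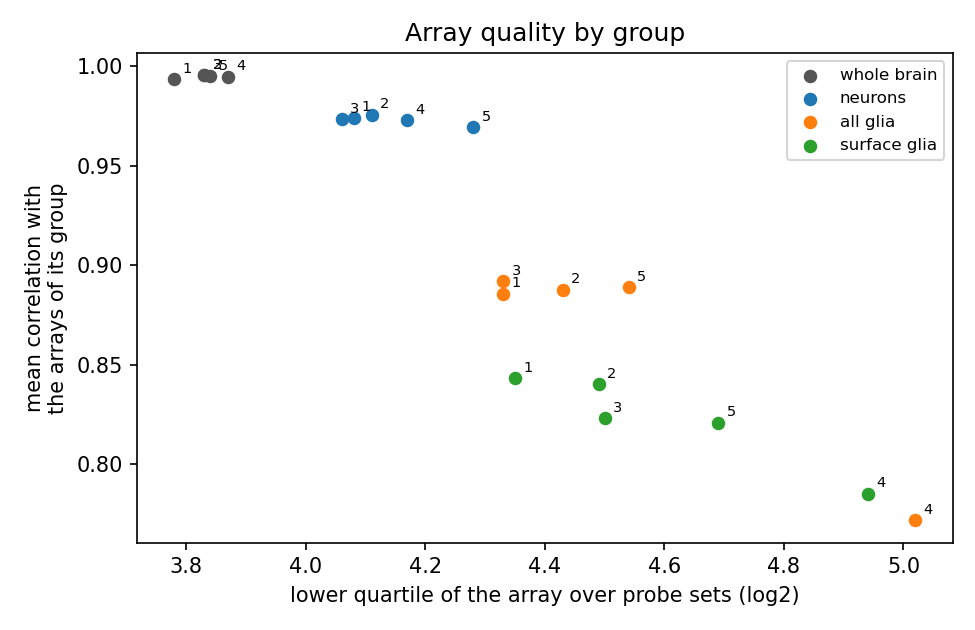
The horizontal axis gives the lower quartile of each array over probe sets (log2) and the vertical axis its mean correlation with the other arrays of its group, with 1 point per array, coloured by group and numbered by replicate. All glia 4 (0.772) and surface glia 4 (0.785) have the lowest correlations and the highest lower quartiles, 5.02 and 4.94.

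Markers of neurons and glia differed between the sorted groups. The glial transcription factor gene repo was at 10.11 ± 0.31 (mean ± SD, log2, n = 5) in whole brain, 5.62 ± 0.94 in neurons, 7.85 ± 0.66 in all glia and 10.66 ± 0.44 in surface glia. The gene moody, which encodes a G protein-coupled receptor of the blood-brain barrier, was at 9.46 ± 0.21, 4.17 ± 1.30, 9.16 ± 2.31 and 11.16 ± 0.51 in the same order. The ABC transporter gene Mdr65 was at 9.61 ± 0.36 in whole brain, 4.31 ± 0.24 in neurons, 10.97 ± 0.65 in all glia and 12.54 ± 0.35 in surface glia. The neuronal gene elav was at 12.78 ± 0.07 in whole brain, 13.04 ± 0.13 in neurons, 12.60 ± 0.41 in all glia and 12.02 ± 0.69 in surface glia, so its level was high in each sorted group. The synaptic genes nSyb and brp were at 12.90 ± 0.25 and 12.29 ± 0.68 in surface glia against 13.47 ± 0.10 and 13.10 ± 0.04 in neurons. The astrocyte gene alrm was at 11.56 ± 0.24 in whole brain and at 4.50 ± 0.87 in neurons, 5.38 ± 2.44 in all glia and 4.84 ± 1.21 in surface glia. The cortex glia gene wrapper was at 9.34 ± 0.19 in whole brain, 4.25 ± 0.58 in neurons, 6.37 ± 1.31 in all glia and 5.82 ± 1.83 in surface glia.

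**Figure D2:**
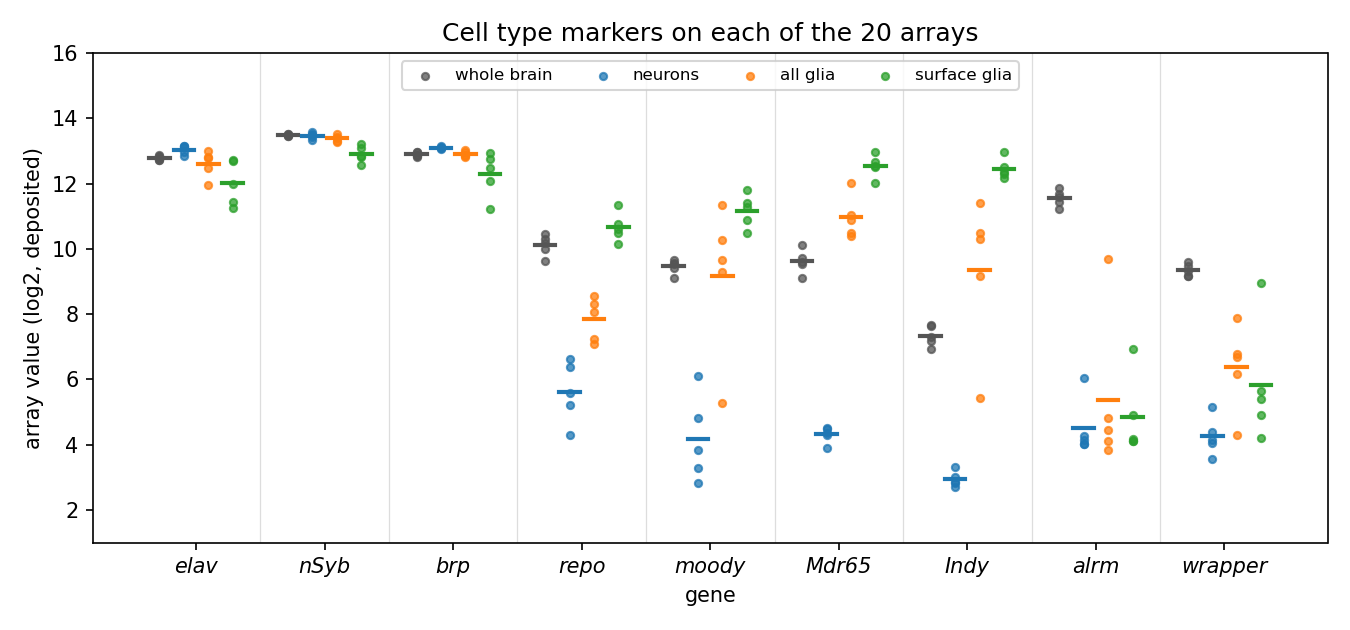
The vertical axis gives the deposited array value (log2) of 9 marker genes, with 1 point per array and a bar at the mean of each group of 5 arrays. Values of elav, nSyb and brp were high in all 4 groups, while repo, moody, Mdr65 and Indy were lowest in neurons.

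Surface glia were compared with neurons to find genes that mark the cells of the blood-brain barrier. The citrate transporter gene Indy rose by at least 8.06 (log2; fitted difference 9.51, SE 0.70, adjusted p = 6.36e-09), from a level within the negative controls in neurons. The collagen IV gene Col4a1 was higher by 8.64 (SE 0.26), Mdr65 by 8.22 (SE 0.28), CG5687 by 8.77 (SE 0.28) and CG10550 by 9.14 (SE 0.49). In neurons the means of CG10550 (3.32), CG5687 (4.25) and Mdr65 (4.31) lay under the mean percentile of the negative controls. The sizes of these 3 differences are therefore uncertain. The papilin gene Ppn rose by at least 7.25, Nplp3 by at least 7.75 and CG16700 by at least 6.51. The largest falls were of the dopamine receptor gene Dop2R at −6.19 (SE 0.77, adjusted p = 9.82e-06), tinc at −5.66 (SE 1.13), the small heat-shock protein gene CG4461 at −5.35 (SE 0.89) and the transcription factor gene fru at −5.21 (SE 1.27). CG4461 was at 11.41 in neurons but within the negative controls in whole brain, at 3.35, so its fall need not mark neurons. On its other probe sets tinc was called lower on 3 (−1.01 to −2.62) and not on 1 (−0.06), and fru was called lower on 1 (−2.25) and not on 5 (−0.996 to 0.46). The sodium-calcium exchanger gene Calx was lower by 5.14 (SE 0.79), the netrin receptor gene unc-5 by 5.05 (SE 1.07), CG8301 by 4.99 (SE 0.82) and CG3548 by 4.90 (SE 0.99). Another probe set of unc-5, at −1.27, did not pass. The means of Dop2R (5.19) and CG3548 (5.11) in surface glia lay under the mean percentile of the controls, so the sizes of these falls are uncertain.

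Of the 18 measured genes of the surface glia and barrier list, 12 were higher in surface glia than in neurons and 0 lower (12 and 2 adjusted over the list alone), among them the transporter genes CG6126 at 8.10, CG3168 at 7.92 and Tret1-1, for trehalose, at 5.76, and moody at 6.99 (SE 0.79, adjusted p = 2.89e-06). The list was called higher, with adjusted p = 9.16e-08, and adjusted p = 0.0247 with an estimated correlation. Of 13 pan-glial genes, 8 were higher and 1 was lower (8 and 1 adjusted over the list alone), with the innexin genes Inx2 at 5.25 and ogre at 4.33, repo at 5.05, bnb at 3.73 and e, a ligase of biogenic amines, at −1.07. The basement membrane and extracellular matrix list had 12 genes higher and 2 lower of 22 (12 and 2 adjusted over the list alone), with the collagen IV gene vkg at 7.75, the laminin gene LanB1 higher by at least 5.44, the integrin gene if at 6.37, mspo at −2.36 and Mp at −1.80. Another probe set of Mp was at 0.73. In the same comparison the hemocyte list had 6 genes higher and 0 lower, the fat body list 7 and 1 and the muscle list 7 and 0. Of 23 septate junction genes, 6 were higher and 9 lower (6 and 9 adjusted over the list alone, 3 and 8 after quantile normalization), with the claudin gene sinu at −4.50, cold at −3.35, l(2)gl higher by at least 1.41 and Nrg at 2.49. Other probe sets of Nrg were at 2.18, which passed, and −0.28. Gli, counted among the higher genes of the septate junction, pan-glial and surface glia lists, lay within the negative controls in both groups. 12 of 38 ABC transporter genes were higher and 1 lower (12 and 1 adjusted over the list alone), with Mdr49 at 5.07 and CG3156 at −2.0. This list passed at adjusted p = 0.00505 but had adjusted p = 0.068 with an estimated correlation. The sugar transporter gene pippin was higher by 6.86, the amino-acid transporter genes blot and CG15279 by 7.15 and at least 4.72, the lipid droplet gene Lsd-2 by 6.43 and the scavenger receptor gene santa-maria by at least 4.51. Of 83 cytochrome P450 genes, 28 were higher and 3 lower (28 and 4 adjusted over the list alone), with Cyp28d1 at 7.24, Cyp28a5 at 6.65 and Cyp4ac1 at −3.49, and the list had adjusted p = 0.136 with an estimated correlation. Of these genes 27 lay within the negative controls in both groups, as did 23 of the next list. Of 69 glutathione and UDP-glycosyl transferase genes, 21 were higher and 1 was lower (21 and 1 adjusted over the list alone), with Ugt302C1 higher by at least 5.30, GstS1 at 5.27 and GstD11 at −2.48, and adjusted p = 0.133 with an estimated correlation.

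Of 24 neurotransmitter receptor genes, 19 were lower in surface glia than in neurons and 0 higher (19 and 0 adjusted over the list alone), with Nmdar1 at −3.53 and 5-HT1A at −3.14. Of 26 pan-neuronal and synaptic genes, 11 were lower and 0 higher (11 and 0 adjusted over the list alone), with lap at −3.05, Rim at −2.56 (others −0.13 and −0.94, which did not pass) and elav at −1.02 (SE 0.26, adjusted p = 0.00648). The genes nSyb at −0.57 and brp at −0.81 differed by less than the minimum of 1, although brp was called lower on 1 of its 3 other probe sets, at −1.12. The glutamate transporter gene VGlut was at −2.97, another probe set of VGlut at 0.17, and the dopamine transporter gene DAT at −2.73. The channel genes Elk and Irk2 went opposite ways, at −3.43 and 3.66, and the peptide gene ITP was higher by 5.92. With an estimated correlation the receptor list had adjusted p = 0.108 and the pan-neuronal list adjusted p = 0.136, so neither passed. Over all probe sets 1959 were higher and 2813 lower in surface glia. Of the higher ones, 163 lay within the negative controls in both groups and 1071 below the median level, and 6 of the 44 negative controls (13.6%) were called higher, with a median difference of 0.66. Of all 18769 probe sets, called or not, 5554 had no overlap between the 5 and 5 arrays, which chance gives for 0.794%. With each array centred on its median, 1350 were higher and 3105 lower, and the median difference of all probe sets, 0.36, moved by −0.14.

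**Figure D3:**
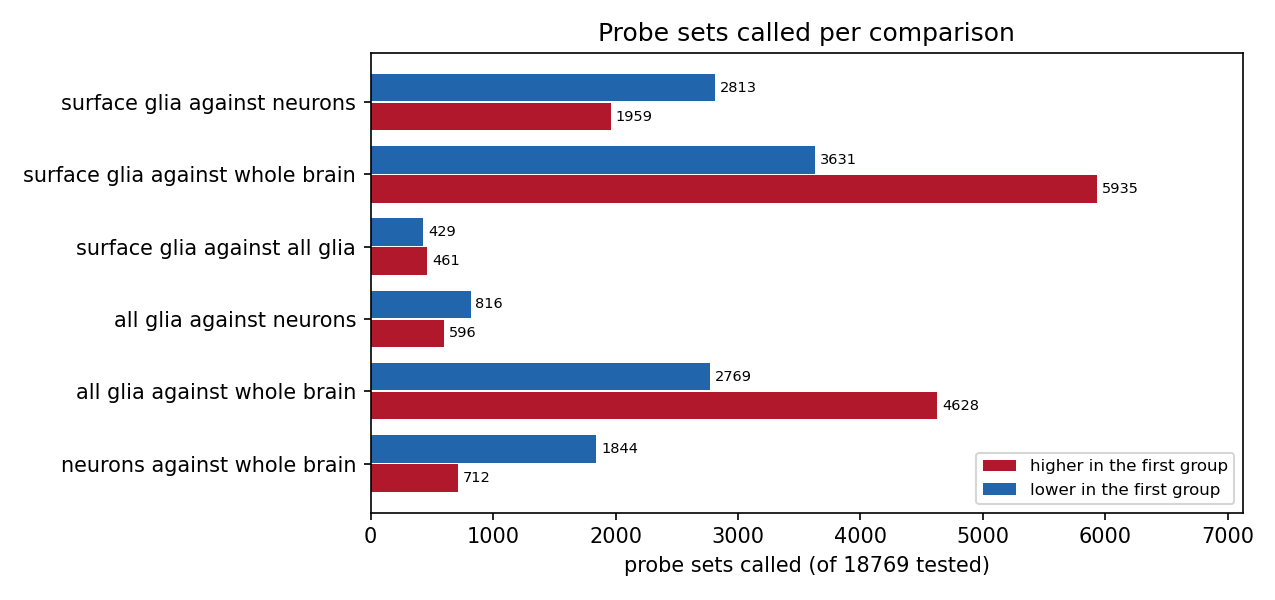
Bars give the number of probe sets called higher (red) or lower (blue) in the first group of each comparison, of 18769 tested, at an adjusted p under 0.05 and a log2 difference of at least 1. The comparison of surface glia with all glia called the fewest, 461 and 429.

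Surface glia were compared with whole brain to find genes enriched over the whole organ. Nplp3 was higher by 7.95 (SE 0.80, adjusted p = 4.57e-07), CG8051 by 6.87 (SE 0.60), bbg, which encodes a PDZ-domain protein, by 6.85 (SE 0.63), LanB1 by 6.04 (SE 0.41) and CG5080 by 5.78 (SE 0.35). The secreted metalloprotease gene AdamTS-A rose by at least 6.04, CG31288 by at least 5.00 and prc by at least 5.05, each from a level within the negative controls in whole brain. The GABA transporter gene Gat fell by at least 6.36 (adjusted p = 5.32e-11) and the insulator protein gene CTCF by at least 3.75, to levels within the negative controls in surface glia. Lower values were also those of Orcokinin at −6.95 (SE 0.56), alrm at −6.72 (SE 0.84), AstC at −6.37 (SE 1.30), CG7646 at −6.31 (SE 0.78), the insulin-like peptide gene Ilp2 at −6.24 (SE 0.76) and Dop2R at −6.17 (SE 0.77). Of 24 neuropeptide genes, 17 were lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 5.50e-07, and adjusted p = 0.0172 with an estimated correlation, and adjusted p = 0.0906 with it without all glia 4 and surface glia 4), with Ilp5 at −5.70 and Pdf lower by at least 4.92. VGlut was at −5.83, with another probe set at 0.36, and the octopamine synthesis gene Tbh at −4.43. Of 11 genes of astrocyte-like and ensheathing glia, 8 were lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation, and adjusted p = 0.102 with it without all glia 4 and surface glia 4), with rumpel at −5.24 and e at −3.86. The cortex glia genes wrapper and zyd were at −3.52 and −3.96. Of 13 pan-glial genes, 6 were lower and 1 was higher, with a list median of −1.01. The list was called lower (adjusted p = 0.00359, and adjusted p = 0.045 with an estimated correlation). Without all glia 4 and surface glia 4 the latter was adjusted p = 0.102. Against the direction of this list, loco, which encodes a regulator of G protein signalling, was higher by 2.76.

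Of the surface glia and barrier genes, 8 were higher in surface glia than in whole brain and 3 lower of 18 (8 and 3 adjusted over the list alone). The list as a whole did not pass (adjusted p = 0.0909). Indy was higher by 5.11 (SE 0.70), CG6126 by 5.05, vkg by 3.15, Tret1-1 by 3.01 and Mdr65 by 2.92, while Oatp58Dc was at −2.31. Gli, counted among the lower ones, lay within the negative controls in surface glia, so no size is given. Of the basement membrane and extracellular matrix genes, 15 were higher and 2 lower (15 and 2 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation, and adjusted p = 0.102 with it without all glia 4 and surface glia 4), with Ppn at 5.16, the perlecan gene trol at 5.11 and Mmp2 at −2.80. Of 7 other probe sets of trol, 2 were called higher (2.65 and 1.44), 3 lay at 0.55 to 0.82 and 2 were at −0.33 and −0.64, and another of Mmp2 was at 1.35. The hemocyte list had 6 genes higher and 0 lower, the fat body list 9 and 2 the muscle list 11 and 1 and the trachea list 11 and 1 against whole brain, with 6 muscle and 4 trachea genes higher after quantile normalization. Of the septate junction genes, 11 were lower and 1 higher (11 and 1 adjusted over the list alone), with sinu at −4.29 and M6 at −2.28. After quantile normalization 5 were lower and 2 higher, and the list median of −1.03 became −0.56. Of 41 ribosomal protein genes, 15 were lower and 4 higher (15 and 4 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation), with RpS18 at −3.29 and RpL32 at −2.82. Over all probe sets 5935 were higher and 3631 lower. Of the higher ones 1825 lay within the negative controls in both groups, 4826 lay below the median level, and 32 of the 44 negative controls (72.7%) were called higher by the same rule, with a median difference of 1.18. After quantile normalization across arrays once more 2784 were higher and 2639 lower, and the median difference of 0.39 moved by −0.21. Of the higher ones, 1378 of 5935 (23.2%) were also higher than in neurons.

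Surface glia were compared with all glia to separate barrier cells from other glia. CG31288 rose by at least 3.57 (fitted difference 5.12, SE 0.55, adjusted p = 3.93e-05). The gene of the Gag-like protein Arc1 was higher by 5.07 (SE 0.48, adjusted p = 7.42e-06), AdamTS-A by 4.46 (SE 0.61), CG7800 by 4.23 (SE 0.56), the acyl-CoA dehydrogenase gene Acadvl by 4.03 (SE 0.55), santa-maria by 3.80 (SE 0.54), olf186-M by 3.78 (SE 0.41) and the nuclear receptor gene svp by 3.77 (SE 0.65). The homeobox gene Ptx1 fell by 5.12 (SE 0.42, adjusted p = 1.19e-06), CG8301 by 4.73 (SE 0.82), aln by 4.12 (SE 0.62) and the polymerase II phosphatase gene Fcp1 by 3.64 (SE 0.51). The peptide gene CCHa2 was at −3.44, CG32532 at −3.43, the kinase gene wnd at −3.40 and Slmap at −3.21. Of the surface glia and barrier genes, 6 were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 0.0917 with an estimated correlation), with Indy at 3.09 (SE 0.70, adjusted p = 0.0122), CG3168 at 2.57 and Mdr65 at 1.57. The difference of moody, 2.00, did not pass (adjusted p = 0.165). The glial genes repo and ogre were higher by 2.82 and 2.21. The extracellular matrix list had 7 genes higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0627 with an estimated correlation), with if at 2.97, trol at 2.87 and mspo at −1.43. The fat body list had 4 genes higher and 1 lower (adjusted p = 0.00803, and adjusted p = 0.104 with an estimated correlation) and the hemocyte list 1 and 0. The muscle list, with 0 calls, had a median of 1.23 (adjusted p = 0.00146, and adjusted p = 0.242 with an estimated correlation). Also higher were the detoxification genes GstE7 by at least 3.04, Ugt302C1 at 3.21 and Cyp6a20 at 3.66, and the transporter genes Oatp74D at 2.63 and pippin at 3.46. Of the neurotransmitter receptor genes, 4 were lower (15 adjusted over the list alone, 10 without all glia 4 and surface glia 4; adjusted p = 0.0917 with an estimated correlation), with Dop2R at −4.58 and Nmdar1 at −3.34. The synaptic genes Rim and futsch were at −2.12 and −1.92. Other probe sets did not pass for Ptx1 (−0.38), AdamTS-A (1.38), aln (−0.06) and Dop2R (−0.45). Some passed and some did not for svp (1.27 against 1.24), Rim (−1.76 against 0.14) and futsch (−1.09 against −0.13). Of 7 other probe sets of trol, 4 passed (1.65 to 3.34) and 3 did not (0.002 to 0.47). Within the septate junction list, sinu was lower by 3.13 and l(2)gl higher by at least 0.66.

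Over all probe sets 461 were higher and 429 lower in surface glia than in all glia. Of all 18769 probe sets, called or not, 477 had no overlap between the arrays, which chance gives for 0.794%. Fitted on the 10 arrays of both groups alone, 22 were higher and 6 lower, and 4 of the 16 genes named for the largest differences passed: CG31288, Arc1, olf186-M and Ptx1, the last on 1 of its 2 probe sets. In simulated data of this comparison the fit of all 20 arrays called 223 of 18569 unchanged probe sets, against 8 with the 10 arrays alone. Without all glia 4, 809 probe sets were lower, and without surface glia 1, 821.

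Genes that separated surface glia from each of the 3 other groups were counted where all 3 comparisons called them the same way. AdamTS-A was higher by at least 5.37 against neurons, at least 6.04 against whole brain and 4.46 against all glia, bbg by 7.66, 6.85 and 3.59, and olf186-M by at least 5.34, 5.20 and 3.78. The sugar transporter gene pippin was higher by 6.86, 5.03 and 3.46, the glutathione transferase gene GstE7 by 4.37, 3.79 and at least 3.04, and the glycosyl transferase gene Ugt302C1 by at least 5.30, 4.94 and 3.21. The vinculin gene Vinc, the repressor gene hry, the asparagine synthetase gene AsnS and the Nimrod receptor gene NimC3 were higher than in all glia by 3.73, 3.20, 3.16 and 3.22, and CG31288, CG13252, CG7800, CG10184 and CG4462 were also among the higher genes named. The claudin gene sinu was lower in each comparison, at −4.50, −4.29 and −3.13, as was the DNA polymerase eta gene PolH, by at least 3.56, 2.40 and 2.02, and Ptx1 at −4.28, −3.31 and −5.12. Another probe set of bbg was at 0.81 against neurons and 0.10 against all glia, which ended both calls, and at 1.29 against whole brain, which passed, and that of Ptx1 was at 0.38 against neurons, 0.74 against whole brain and −0.38 against all glia, so that no call of Ptx1 was kept on it. Also lower in all 3 were CG8301, wnd, CG32532, Fcp1 and CG16854, at −4.73, −3.40, −3.43, −3.64 and −2.77 against all glia. In total 291 probe sets of 256 genes were higher and 310 of 250 genes lower. Fits on only the arrays of each comparison gave 15 and 5, while without surface glia 1 the lower ones were 651 and without all glia 4 they were 601. Fitted on the arrays of both glial sorts alone, AdamTS-A, CG7800, CG8301, wnd, CG32532 and Fcp1 lost their call against all glia. Another probe set of AdamTS-A, at 1.38 against all glia, did not pass. The level of hry was 4.66 in all glia 4, below the 9.06 to 9.77 of the other all-glia arrays. The fat body list also had more genes higher than lower in surface glia in all 3 comparisons. These were 7 and 1 against neurons, 9 and 2 against whole brain and 4 and 1 against all glia. Whether RNA of other tissues in the surface-glia sort gave some of the calls of this paragraph was not tested.

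**Figure D4:**
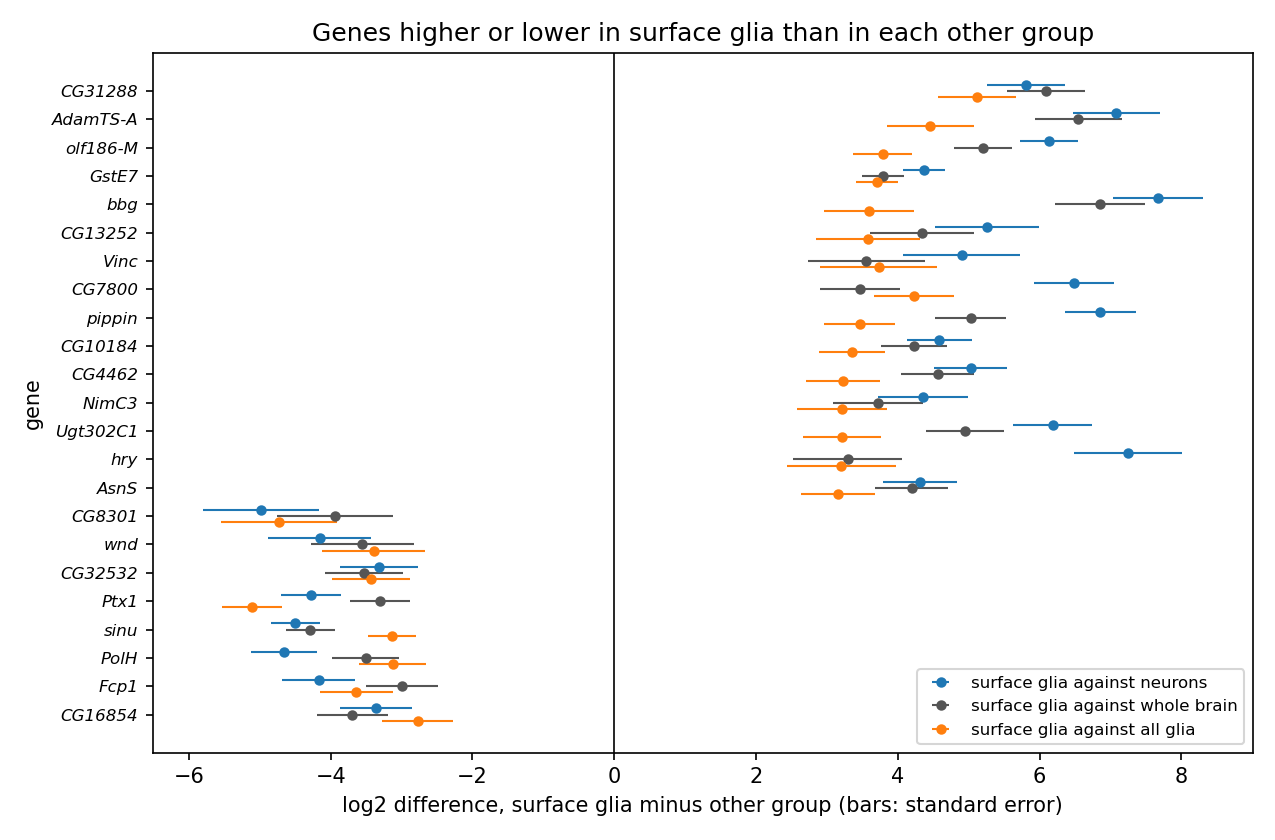
The horizontal axis gives the log2 difference of surface glia minus neurons (blue), whole brain (grey) and all glia (orange) for the 23 named genes called the same way in all 3 comparisons, with bars of 1 standard error. The 15 genes at the top were higher in surface glia and the 8 at the bottom lower.

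All glia were compared with neurons to find genes of glia in general. Col4a1 was higher by 7.39 (SE 0.26, adjusted p = 7.69e-13), CG10550 by 6.87 (SE 0.49), CG6126 by 6.79 (SE 0.31), Cyp28d1 by 6.77 (SE 0.26) and vkg by 6.75 (SE 0.43), while Nplp3, Ppn and CG16700 rose by at least 6.13, 5.89 and 5.15. RhoGAP102A fell by at least 4.24, CG33098 by at least 1.90 and Not11 by at least 1.39, to levels within the negative controls. CG4461 was at −4.95 (SE 0.89), the muscle gene bt at −4.22 (SE 1.09), Sol1 at −3.90 (SE 0.57), the kinesin gene cmet at −3.86 (SE 0.74) and the Pax6 gene toy at −3.71 (SE 0.49). The means of bt (3.50) and cmet (4.96) in all glia lay under the mean percentile of the negative controls. So did those of CG10550 (3.32) and CG6126 (4.21) in neurons, and the sizes of these differences are uncertain. Another probe set of CG33098 (−0.69) did not pass, while of the others 1 of Sol1 (−2.53) and 1 of toy (−3.62) passed and 1 of each (−0.21 and −1.08) did not. Of the pan-glial genes, 7 were higher and 0 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation), with bnb at 4.52, Inx2 at 3.66 and repo at 2.23. Of the surface glia and barrier genes, 11 were higher and 1 was lower (11 and 1 adjusted over the list alone; adjusted p = 0.0139 with an estimated correlation), with Mdr65 at 6.65, Indy higher by at least 4.97, moody at 4.99, Tret1-1 at 4.64 and Lac at −1.95. The hemocyte list had 4 genes higher and 0 lower (adjusted p = 0.0352), the fat body list 3 and 1 (adjusted p = 0.0238) and the trachea list 2 and 0 (adjusted p = 0.0131), and with an estimated correlation none of these 3 passed. The heat and dissociation stress list had 0 genes higher and 2 lower, or 0 and 0 after quantile normalization. It passed as lower at the preset correlation (adjusted p = 0.00352) but not with an estimated one. The cortex glia genes zyd and wrapper were higher by 3.72 and 2.11, and alrm, at 0.88, did not pass (adjusted p = 0.416). Of the pan-neuronal and synaptic genes, 0 were lower in all glia than in neurons and 0 higher (0 and 0 adjusted over the list alone), with elav at −0.44 (SE 0.26, adjusted p = 0.204). The monoamine transporter gene prt was at −1.53 and the early response gene Hr38 at −1.78 (another probe set, at −1.5, did not pass), while ITP and Irk2 were higher by 3.95 and 2.99. The mean of prt in all glia, 4.36, lay under the mean percentile of the negative controls. The size of its fall, and whether it reached the minimum difference, are therefore uncertain. Over all probe sets 596 were higher and 816 lower, and with each array centred on its median 415 and 1022, the median difference of 0.27 moving by −0.15. Without neurons 1 they were 372 and 436. Of the 596 higher probe sets, 469 were also higher in surface glia than in neurons, where simulated unchanged groups against the same neuron arrays shared 0.55 on average and independent lists of these sizes would share 62.2. Without neurons 1, 308 were shared. With the neuron arrays split between both comparisons, 226 to 259 probe sets were shared over 10 splits, against 19.0 for independent lists. The simulated groups did not differ from neurons, so little sharing was built in. The all-glia sort may hold surface glia, and both glial sorts share the 500 rpm shaking and a raised background. The overlap cannot tell genes of glia in general apart from these.

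All glia were compared with whole brain to find what the sort enriched. Nplp3 was higher by 6.32 (SE 0.80), LanB1 by 5.25 (SE 0.41, adjusted p = 2.22e-08), CG5080 by 4.91 (SE 0.35), CG6912 by 4.89 (SE 0.42), the immune peptide gene BomS2 by 4.36 (SE 1.21), the inositol oxygenase gene Miox by 3.94 (SE 0.31) and CG4250 by 3.88 (SE 0.36). The monoamine transporter gene Vmat was higher by 4.01 on 1 probe set, with others at 0.72, −0.97 and −1.94. Gat fell by at least 6.44 (adjusted p = 4.26e-11) and CTCF by at least 3.83, to levels within the negative controls. CG12239 was at −6.73 (SE 1.14), vir-1 at −6.65 (SE 0.82), RpS29 at −6.52 (SE 0.65), Ilp2 at −6.32 (SE 0.76), alrm at −6.18 (SE 0.84) and Orcokinin at −6.05 (SE 0.56). Other probe sets of RpS29 (−0.30 and −0.40) did not pass, and of CTCF 1 passed (−3.64) and 1 did not (−0.90). Of the pan-glial genes, 8 were lower in all glia than in whole brain and 1 was higher (9 and 1 adjusted over the list alone; adjusted p = 0.00694 with an estimated correlation), with repo at −2.27 and loco at 1.66. Of the astrocyte-like and ensheathing glia genes, 8 were lower and 0 higher (9 and 0 adjusted over the list alone; adjusted p = 0.00996 with an estimated correlation), with rumpel at −4.92. The cortex glia genes zyd and wrapper were at −2.52 and −2.98. Of the surface glia and barrier genes, 7 were higher and 4 lower (7 and 4 adjusted over the list alone), with Indy at 2.02 and Tret1-1 at 1.89, while moody did not pass at −0.30. Ilp5 was at −6.00 and Pdf at −4.48, and of the ribosomal protein genes 21 were lower and 5 higher (21 and 5 adjusted over the list alone; adjusted p = 0.0451 with an estimated correlation, and adjusted p = 0.0763 with it without all glia 4 and surface glia 4), with RpS18 at −4.40 and RpL32 at −3.84. After quantile normalization 16 ribosomal protein genes were lower and 1 was higher. The hemocyte and trachea lists had 7 and 8 genes higher, or 4 and 4 after quantile normalization, and the fat body list 5. The receptor gene nAChRalpha1 was lower by 2.28, and another probe set, at −0.46, did not pass. Over all probe sets 4628 were higher (2840 without all glia 4) and 2769 lower, with 1479 of the higher ones within the negative controls in both groups and 28 of the 44 negative controls called higher. After quantile normalization across arrays once more 1927 were higher and 1942 lower, the median difference of 0.31 moving by −0.15, and the median of the pan-neuronal and synaptic list changed sign, from −0.18 to 0.14.

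Neurons were compared with whole brain as the reference sort. CG4461 rose by at least 7.69 (adjusted p = 1.51e-06) and mthl8 by at least 3.64, from levels within the negative controls in whole brain. CG6912 was higher by 5.26 (SE 0.42), cmet by 4.23 (SE 0.74), the small heat-shock protein gene l(2)efl by 4.22 (SE 1.15), bt by 3.91 (SE 1.09) and CG12716 by 3.91 (SE 0.52). The non-coding RNA gene lncRNA:alphagamma-element:CR32865 was higher by 4.16 (SE 0.21, adjusted p = 3.38e-11). Other probe sets of l(2)efl, at 0.38 and 0.30, did not pass. CG40470 was at −8.13 (SE 1.09), Gat at −7.45 (SE 0.37, adjusted p = 2.44e-11), Cyp28d1 at −7.39 (SE 0.26), alrm at −7.06 (SE 0.84), CG7888 at −6.74 (SE 0.52), the sialic acid synthesis gene Csas at −6.73 (SE 0.58), CG31706 at −6.69 (SE 0.46) and Ilp5 at −6.65 (SE 0.28). In neurons the means of CG40470 (3.48) and Gat (4.14) lay under the mean percentile of the negative controls. The sizes of their falls are therefore uncertain. Of the 13 pan-glial genes, 11 were lower in neurons and 0 higher (11 and 0 adjusted over the list alone; adjusted p = 1.58e-05 with an estimated correlation), with Inx2 at −5.76, bnb at −4.74 and repo at −4.50. Of the surface glia and barrier genes, 11 were lower and 0 higher (11 and 0 adjusted over the list alone; adjusted p = 0.00242 with an estimated correlation), with Col4a1 at −5.83, Mdr65 at −5.30, moody at −5.29, vkg at −4.60 and Indy lower by at least 2.95. The cortex glia genes zyd and wrapper were at −6.24 and −5.09. Of the neuropeptide genes, 12 were lower and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 0.00123 with an estimated correlation), with Ilp2 at −6.55 and Pdf lower by at least 5.75. Of the ribosomal protein genes, 25 were lower and 0 higher (25 and 0 adjusted over the list alone; adjusted p = 0.00156 with an estimated correlation), with RpS18 at −5.24 and RpL32 at −4.30. Of the pan-neuronal and synaptic genes 5 were lower and 0 higher (5 and 0 adjusted over the list alone), with Nlg2 at −2.95 and other probe sets of it at 0.65 and −0.74. The genes elav at 0.26, nSyb at −0.03 and brp at 0.21 did not pass, although brp was called higher on 1 of its 3 other probe sets, at 1.08. The histamine synthesis gene Hdc was lower by 3.02, Irk2 by 5.03 and Lsd-2 by 4.86, while Elk was higher by 1.63 and the heat-shock gene Hsp27 by 2.82. The rise of Hsp27 was not particular to neurons. Its mean was 9.08 in whole brain, 11.90 in neurons, 11.29 in all glia and 12.05 in surface glia. Of 12 measured heat and dissociation stress genes, 4 were higher and 2 lower in surface glia than in whole brain. In all glia 1 was higher and 1 lower, and the list passed in neither (adjusted p = 0.665 and adjusted p = 0.662). Over all probe sets 712 were higher and 1844 lower in neurons than in whole brain. With each array centred on its median they were 1345 and 1605, the median difference of 0.27 moving by 0.14. Fitted on the 10 arrays of both groups alone, 1238 were higher.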

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

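The tests that weigh the exchange of 2 arrays were chosen after the result was seen.

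Single arrays stood far from the other 4 of their group in 28 of 467 groups of values tested (6.0%). Chance gives about 1 in 20. All glia 4 had a median of 6.1 (log2), against 5.69 to 5.8 in the other all-glia arrays, and a mean correlation with its group of 0.772. The others were at 0.886 to 0.892. In the same array hry was at 4.66, trol at 6.22 and if at 4.04, each below the others. In surface glia 1, tinc was at 10.29, CCHa2 at 7.05 and Tbh at 6.89, each above the other surface-glia arrays. In surface glia 4, e was at 7 and CG15279 at 7.48, in surface glia 2 tim was at 8.54, and in surface glia 5 alrm was at 6.92. In all glia 5, alrm was at 9.7 and Pdf at 10.63, and in all glia 2 Ilp2 was at 9.42. In neurons 2, CG40470 was at 6.25, bbg at 5.48, 5-HT1A at 11.89 and BomS2 at 5.59. In neurons 4, alrm was at 6.05 and CG7888 at 6.54, in neurons 3 Hdc was at 5.68 and in neurons 5 Ugt302C1 at 3.2. In whole brain 1, vir-1 was at 12.25 and Vinc at 7.97. In whole brain 4 e was at 9.95 and Nlg2 at 11.39, and in whole brain 5 CG10184 was at 4.29.

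Outside the probe sets compared, 3 control probe sets of the array had signal in every sorted array above every whole-brain array. The sorted cells came from lines with a green fluorescent protein and the whole brains from wild-type flies. What these probe sets detect was not examined, and whether the signal came from a transgene of the sorted lines was not tested. The smallest gap between the sorted and the whole-brain arrays was 3.73 (log2) for the first, AFFX-Dm-AF292560-1_s_at, 1.91 for AFFX-Dm-K01486-1_at and 8.38 for AFFX-Dm-M62653-1_s_at. Their means in whole brain were 1.89, 2.61 and 2.25, and in neurons 11.16, 12.63 and 12.70. In all glia they were 9.25, 9.58 and 11.67, and in surface glia 10.41, 8.90 and 11.72. In surface glia AFFX-Dm-K01486-1_at ranged from 4.59 to 11.37.

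Other splits of the same 10 arrays were fitted in the same way, 100 for each comparison with the real one included. For surface glia against neurons 1 split, the real one, called as many probe sets (4772, highest other 451). For surface glia against whole brain it was 1 (9566, highest other 4229), for all glia against neurons 1 (1412, highest other 41), for all glia against whole brain 1 (7397, highest other 2) and for neurons against whole brain 1 (2556, highest other 0). For surface glia against all glia 4 splits called as many as the real one, itself included (890, highest other 2056). Among 100 groupings of all 20 arrays, 2 gave as many probe sets higher in surface glia than in each other group (291, highest other 722) and 2 as many lower (310, highest other 702). For probe sets higher in both glial sorts than in neurons it was 1 (469, highest other 0). Each share was under the 5 in 100 set beforehand as arguing against chance. For surface glia against all glia, and for the counts against each other group, other splits called more than the real one, so chance is not excluded there. Splits that call over 2 times the real count point to a structure of the samples. The split with 4229 probe sets set surface glia 1 with 4 of the whole-brain arrays.

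The split of the glial sorts that called 2056 probe sets exchanged surface glia 1 and all glia 4. Exchanged labels are argued against, since the surface glia and barrier genes of all glia 4 had a median of −1.6 (log2) from the other surface-glia arrays, with 2 of 18 above them. More RNA of neurons in surface glia 1 is a candidate explanation: the pan-neuronal genes there had a median 0.79 above the other surface-glia arrays, with 24 of 26 above, and the receptor genes 1.37. Weak signal over background in all glia 4 is another, since its standard deviation over probe sets, 2.0 (log2), was the lowest of the 20 arrays. Both may hold together, and no biological explanation was tested.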

How the results depend on the processing

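The comparisons, thresholds, gene lists and alternatives were fixed before the data were examined. Only 3 alternatives were chosen after seeing the data: the counts and the list tests without all glia 4 and surface glia 4, and the counts without probe sets within the negative controls in both groups.

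Over the 315 differences of named genes, no called difference of the same probe set reversed under any alternative, and a trend or robust estimate of the spread changed 0 calls. A fit on only the arrays compared ended 44 calls, the treat test against a difference of 1 ended 68, an adjusted p under 0.01 ended 24, array weights 16, quantile normalization 7 and centring 3. Over the 6300 differences from 20 fits without 1 array each, 69 calls were lost, 5 gained and 0 reversed, while 4 differences that were not called changed sign. Of 86 differences on other probe sets of a gene, 35 kept the call or its absence, 34 lost the call, 2 gained one, 1 that was not called changed sign and 14 reversed. They reversed fru (0.46), Ptx1 (0.38), Mp (0.73), Nrg (−0.28) and VGlut (0.17) in surface glia against neurons. Those of surface glia against whole brain were Ptx1 (0.74), VGlut (0.36), trol (−0.33 and −0.64) and Mmp2 (1.35), and against all glia Rim (0.14). They also reversed Vmat (−0.97 and −1.94) in all glia against whole brain and Nlg2 (0.65) in neurons against whole brain, and the cause was not tested. Of the 198 list tests, 73 calls were lost with an estimated correlation, 25 lost and 35 gained among genes above the median level, and 4 lost and 55 gained with fry. Without all glia 4 and surface glia 4, 6 were lost and 3 gained, and 9 of the 23 that passed with an estimated correlation were lost with it.

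Fitted on only the arrays compared, surface glia against all glia gave 22 higher and 6 lower, neurons against whole brain 1238 higher, and the probe sets higher and lower in surface glia than in each other group were 15 and 5. Array weights gave 272 higher in surface glia than in all glia, 1245 in neurons than in whole brain and 188 in surface glia than in each other group. In simulated surface glia against all glia, fitting all arrays called 223 unchanged probe sets, and fitting only the arrays compared called 8. The latter called 109 of 200 changed ones, so real changes can be lost too. The median spread within groups was 0.59 in all glia, 0.58 in surface glia, 0.27 in neurons and 0.15 in whole brain. A shared spread can thus raise the calls of the first comparison and lower those of neurons against whole brain. How much of each change it accounts for was not tested.

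Without probe sets under the median level, 875 were higher in surface glia than in neurons, 1075 in surface glia than in whole brain, 382 in all glia than in neurons, 750 in all glia than in whole brain and 422 in neurons than in whole brain. Without the lowest 25% of probe sets, 3426 were higher in surface glia and 2796 in all glia than in whole brain. These filters test fewer probe sets. The weaker signal over background of the sorted arrays limits what can be said of dim probe sets.

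Quantile normalization once more gave 2784 higher in surface glia than in whole brain, 449 lower in all glia than in neurons and 1927 higher in all glia than in whole brain. Centring gave 1345 higher in neurons than in whole brain. A single value per symbol gave 3438 higher in surface glia, 2409 in all glia and 378 in neurons than in whole brain, with fewer features tested.

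With no minimum difference, 5934 were higher in surface glia than in neurons, 1704 in all glia than in neurons, 7117 in all glia than in whole brain, 2190 in neurons than in whole brain and 1487 in both glial sorts than in neurons. At an adjusted p under 0.01, surface glia against neurons gave 1605 lower, surface glia against all glia 235 higher and 144 lower, all glia against neurons 280 and 243. It gave for neurons against whole brain 365 higher, each other group 148 and 105, and both glial sorts 244. The treat test gave 417 higher and 322 lower for surface glia against neurons, 539 and 1117 against whole brain, 22 and 8 against all glia, and 121 and 42 for all glia against neurons. It gave 81 and 635 for all glia against whole brain, 49 and 593 for neurons against whole brain, 13 and 7 for each other group, and 110 for both glial sorts.

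Without all glia 4 and surface glia 4, 717 were lower in surface glia than in all glia, 2881 higher in all glia than in whole brain and 504 lower in surface glia than in each other group. The cause was not tested.

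Leaving out 1 array at a time gave 1445 to 2839 higher and 2344 to 3078 lower for surface glia against neurons, 4965 to 6441 and 3388 to 3814 against whole brain, and 358 to 561 and 316 to 821 against all glia. It gave 372 to 836 and 436 to 1094 for all glia against neurons, 2840 to 5138 and 2538 to 2869 against whole brain, and 500 to 849 and 1622 to 1972 for neurons against whole brain. The probe sets higher and lower in surface glia than in each other group were 228 to 357 and 228 to 651, and those of both glial sorts 308 to 543. Arrays that moved a count by over 1.5 times were neurons 1 (all glia against neurons 372 and 436, both glial sorts 308), neurons 2 (491 lower) and neurons 3 (391 and 471). Without all glia 4 there were 809 lower in surface glia than in all glia, 535 lower in all glia than in neurons, 2840 higher in all glia than in whole brain and 601 lower in surface glia than in each other group. Without surface glia 1 there were 821 and 651 lower for the first and last of these.

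The replicate numbers did not pair the arrays: 2 of 30 pairs of the same number correlated over 0.1 in their deviations from the group means (−0.019 to 0.378, median 0.033), and 6 of 20 arrays correlated best with their own number. With the replicate number as a block, no count moved by over 1.5 times. Surface glia against neurons gave 1981 higher and 2922 lower, against whole brain 5939 and 3692 and against all glia 451 and 432. All glia gave 658 and 1043 against neurons and 4630 and 2826 against whole brain, neurons against whole brain 742 and 1886, each other group 282 and 310, and both glial sorts 514.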

Other observations

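The tests on astrocyte-like and ensheathing glial genes, the error in the test on short genes and the random lists for the correlation between sorts were chosen after the result was seen.

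Genes of the circadian clock differed between surface glia and neurons in both directions. Clk, which encodes an activator of the clock, was higher by 4.92, vri by 2.79 and tim by 2.62. Of the 9 measured clock genes, 4 were higher and 1 was lower (4 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.843), with a median of −0.26 and a mean of 0.90. Against whole brain Clk was higher by 2.31, vri by 2.53 and tim by 2.52, and against all glia Clk by 3.37. Of 16 immune response genes 7 were higher in surface glia than in neurons and 1 was lower (adjusted p = 0.0187, adjusted p = 0.136 with an estimated correlation). The serpin gene nec was at 6.56, BomS2 at 4.62 and pirk at 3.09. The fat body list had 7 higher and 1 lower of 13 in surface glia against neurons, with the yolk protein genes Yp2 at 5.56 and Yp1 at 5.42. Against whole brain Yp2 was higher by 4.73, Yp1 by 3.80 and apolpp lower by 2.71. The hemocyte list had 6 higher and 0 lower of 15, with srp higher by at least 1.92 and NimC1 at 2.61, and the muscle list 7 higher and 0 lower of 19, with Act79B at 5.27. The gluconeogenesis gene Pepck1 was higher by at least 3.36 and RpS18 by 1.95 in surface glia than in neurons. In all glia against neurons BomS2 was higher by 6.41 and Yp1 by 3.12.

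The remaining lists are given for surface glia against neurons. The transmitter synthesis and transport list had 0 higher and 9 lower of 15 (5 lower without all glia 4 and surface glia 4), and the ion channel list had 1 higher and 11 lower of 24. The cortex glia list had 3 higher and 1 lower of 6, and the innexin list had 2 higher and 0 lower of 7. The sugar and monocarboxylate transporter list had 7 higher and 3 lower of 24, and the amino-acid transporter list had 6 higher and 6 lower of 24 (3 lower after quantile normalization). The organic anion and cation transporter list had 8 higher and 1 lower of 18, and the lipid carrier list had 7 higher and 2 lower of 22. The glycolysis list had 7 higher and 0 lower of 15, and the oxidative phosphorylation list had 0 higher and 0 lower of 20. The heat and dissociation stress list had 0 higher and 2 lower of 12, and the cell cycle list had 3 higher and 0 lower of 9. The photoreceptor list had 3 higher and 5 lower of 17, and the trachea list had 2 higher and 1 lower of 14. The sex-linked list had 5 higher and 2 lower of 10, and the eye pigment list had 1 higher and 0 lower of 4. The oxidative phosphorylation list, with 0 calls in limma, had 2 genes higher and 0 lower at an unadjusted p under 0.05, and its median of 0.09 changed sign with each array centred. The photoreceptor list had a median of 0.45 and a mean of −0.39. At the preset correlation, passing lists of this paragraph and the last were immune response, transmitter (adjusted p = 2.77e-04), ion channel, cortex glia, innexin, sugar transporter, organic anion and cation transporter, glycolysis, trachea, fat body, hemocyte and muscle. With an estimated correlation none of the lists of this paragraph and the last passed. The ribosomal protein list had 12 genes higher of 41 (21 after quantile normalization and 8 with each array centred), and passed at the preset correlation (adjusted p = 1.17e-06) but not with an estimated one (adjusted p = 0.0808).

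Genes of astrocyte-like and ensheathing glia were lower in all glia than in whole brain, with a median of −1.94. A loss shared by transcripts of the same whole-brain level is argued against as the whole cause, since 0.56% of 10000 level-matched random lists had a median as low, although these lists also fell, with a median of −0.69. Dilution of glial transcripts by RNA of other cells cannot be told apart: the pan-glial and cortex glia lists had medians of −1.99 and −1.99, as low as the astrocyte list, while the surface glia and barrier list, whose members went both ways, had one of 0.31. On the surface list alone, as the test was first written, it would have been argued against, and the other lists were added after their values were known. The sort may also have recovered fewer astrocyte-like than surface glia. For this hypothesis, the difference of −2.26 between the medians of these lists had a one-sided permutation p = 0.00022 over genes. That p treats the genes as independent and does not measure the spread between arrays. Genotype and dissociation were not tested.

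Ribosomal protein genes were lower in neurons and all glia than in whole brain, and had a median of −0.38 in surface glia (adjusted p = 0.196 with an estimated correlation). Loss of cell types in the sorts cannot be told apart: the differences correlated across the 41 genes at 0.949 or more, and 0% of 2000 level-matched random lists reached this (upper limit 0.777). The 0.5 set beforehand as arguing against it was judged too low after the values were seen, since 54.75% of these lists reached it with the same whole-brain arrays subtracted, and a cell type missing from every sort would also lower the same genes in each. Under-recovery of transcripts from short genes cannot be told apart either. In neurons, all glia and surface glia, 515 other short genes lay at −0.41, −0.36 and −0.232 from longer genes of the same level. The bootstrap error of the last, 0.06, was added after the value was seen and spans the 0.25 set beforehand. Without that error this explanation would have been argued against. The ribosomal list lay at −1.39, −0.63 and 0.16 from the same longer genes. Of its 41 genes 18 are short, but gene length includes introns, so neither this count nor the short genes show the length of the transcripts. A loss shared by transcripts of the same level stays open for surface glia, where 95.86% of level-matched random lists had a median as low, against 0% in neurons and 0.23% in all glia.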
